A study of Mus musculus and Homo sapiens with 9 samples.

How the data were processed

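Total RNA of 9 samples was hybridised to GeneChip Mouse Gene 2.0 ST arrays (3 SVEC4-10 and 3 mouse LEC) and GeneChip Human Gene 2.0 ST arrays (3 human LEC), with 1 label colour, per the labels' protocols. The deposited values are log2 expression values, made by the authors with RMA in Transcriptome Analysis Console 3.0 per the submitters' processing notes. RMA corrects the background of each array, makes the distributions of the arrays equal and summarises the probes of a probe set by median polish. The mouse and human values stand in separate tables with different quartiles (25th percentiles near 3.9 in mouse and 1.99 in human). Expression levels were therefore tested between groups only within the mouse table. The human mean entered the correlations across species and the comparison with random lists. The summary level, filters, annotation and genome build are not given in the sources used here, so no coordinates are printed. The values carry no detection calls, so a dim gene cannot be called absent, and the fold of a gene that is dim in 1 group is compressed.

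Groups and replicate numbers were taken from the sample titles. Probe sets were named through the platform annotation: of 41345 mouse probe sets, 23521 had 1 symbol, 1814 several and 16010 were not listed, and of 53617 human probe sets 16098 had 1 symbol and 37519 were not listed. A probe set with several symbols was given no name. Of the 23521 mouse probe sets with 1 symbol, 23328 matched the mouse gene table of assembly GRCm38.p6 by gene number, and 0 symbols changed. Where several probe sets named 1 gene, the one with the highest mean over the arrays stood for it. This applied to 1082 mouse genes. Of these, 185 had a called probe set, 152 had both called and uncalled ones, and 0 were called in both directions. This left 22180 mouse and 14884 human genes, without a filter on dim genes. Human genes were matched to mouse genes by symbol in upper case with a few listed exceptions (10085 genes).

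Each gene was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3, statmod 1.5.0) on the deposited log2 values, mouse LEC minus SVEC4-10, two-sided, with Benjamini-Hochberg adjustment over all 22180 genes. A gene was called at an adjusted p under 0.05 and a difference of at least 2-fold. Adjusted p-values of single genes come from limma. Gene lists were tested with camera of limma (preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 23 lists. An estimated correlation and fry were run beside it. camera compares a list with the other genes of the arrays. fry tests whether the genes of a list move, on balance, in 1 direction. The 23 lists were lymphatic, blood vascular and pan-endothelial markers, fibroblast, smooth muscle and pericyte, keratinocyte and leukocyte markers, proliferation and E2F targets, p53 targets, cell-cycle inhibitors, interferon-stimulated, antigen presentation, chemokine and adhesion, angiogenic, cell junction, basement membrane and integrin, endothelial-to-mesenchymal transition, cholesterol synthesis, glycolysis and hypoxia, glucocorticoid-induced, ERK-induced, housekeeping and sex-linked genes.

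The text names the 8 genes with the largest difference in each direction among called genes whose groups do not overlap, leaving out predicted loci, small RNAs and receptor segments. It also names up to 3 called genes of each list in its direction and up to 2 in the other, and a fixed set of endothelial, cell cycle and sex-linked genes. Other list members are named where they complete a small count or give an uncalled value, and these were chosen after their values were seen. No human sex-linked gene was examined. The lists, tests, naming rule and alternatives were fixed before the data were examined.

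Similarity between species was the Pearson correlation across matched genes of each mouse array with the mean human array, with an exact permutation test of the 6 correlations. The human level of called genes was set against 10000 random lists of the same size matched on mouse level in 20 bins. The fit was tested on simulated data with 22180 genes and the spread of these arrays. It recovered 93% of 100 genes changed by 1.5 on the log2 scale and 100% of 100 genes changed by 3, with 0 false calls among unchanged genes. In simulated lists, camera called the 1 moved list and 0 unmoved lists. The simulated genes varied independently and no gene outside that list changed, so this does not test the preset correlation. The alternatives were other scalings, filters on dim genes, the mean of a gene's probe sets, a variance trend, array weights, the sample number as a block, other fold minimums, every probe set, other list tests, a Spearman correlation, other gene selections and leaving out each array in turn. Plots were drawn with matplotlib 3.10.9.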

Results

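Expression was measured on 9 arrays in 3 groups of 3. SVEC4-10 is a mouse endothelial cell line transformed with SV40, which the labels call a lymphatic line. Mouse LEC were primary lymphatic endothelial cells from the skin dermis of C57BL/6 mice, and human LEC were primary human lymphatic endothelial cells. The 6 mouse arrays share 1 design and the 3 human arrays another. Values are log2 RMA expression values, so a difference of 1 is 2-fold. The mouse values covered 41345 probe sets, of which 23521 named exactly 1 gene, giving 22180 genes. The human values covered 53617 probe sets and 14884 genes. Array medians over all probe sets lay between 5.14 and 5.17 in mouse and between 3.25 and 3.28 in human. The number of arrays limits the precision. The SVEC4-10 line grew in a plain medium with serum, while both primary cultures received endothelial growth factors, heparin and hydrocortisone, so medium and cell type cannot be told apart.

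Arrays of 1 group were close to each other. Correlations across genes, which are not independent replicates, were 0.992 to 0.994 among mouse LEC and 0.994 among SVEC4-10. Between the mouse groups they were 0.914 to 0.917. The median SD of a gene over the 3 arrays was 0.117 in mouse LEC and 0.119 in SVEC4-10. The human arrays correlated at 0.998 to 0.999, but 29041 of the 53617 human probe sets (54.2%) held 1 identical value on all 3 arrays. A human SD of 0 is therefore no estimate of replicate error. The labels call the arrays triplicates and do not say whether they came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

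The comparison of mouse LEC with SVEC4-10 asks how the line differs from primary cells of the type it stands for. All 25 measured pan-endothelial genes were higher in mouse LEC, and 12 of 22 fibroblast genes and the uroplakin genes Upk1b and Upk3b were higher in SVEC4-10, while the lymphatic list was not called. Cdh5, the VE-cadherin of endothelial junctions, measured 12.63 ± 0.04 (SD, n = 3) in mouse LEC and 4.74 ± 0.12 in SVEC4-10, a 237-fold difference. Dcn, encoding the collagen-binding proteoglycan decorin, measured 3.96 ± 0.44 in mouse LEC and 11.33 ± 0.07 in SVEC4-10, a 166-fold difference in the other direction. Glucocorticoid-induced genes were also higher in mouse LEC, and cholesterol synthesis, proliferation and interferon-stimulated genes in SVEC4-10, as lists.

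Of 22180 genes tested with limma, 8021 had a Benjamini-Hochberg adjusted p under 0.05 and 2548 also differed by at least 2-fold. Of these, 1180 were higher in mouse LEC and 1368 in SVEC4-10. At least 16-fold differences were found for 145 genes higher in mouse LEC and 98 higher in SVEC4-10. The groups did not overlap for any of the 2548 called genes. They did not overlap for 10424 of all tested genes (47.0%), where chance gives 10%. The median difference over all genes was 0.0023 on the log2 scale.

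The 8 named genes with the largest differences toward mouse LEC were Ms4a6d (log2 difference 9.29 ± 0.21, SE), Chil5 (8.21 ± 0.08), Cdh5 (7.89 ± 0.09), Emcn (7.85 ± 0.23), Tc2n (7.54 ± 0.10), Calcrl (7.34 ± 0.11), Lyve1 (7.34 ± 0.10) and Ceacam1 (7.29 ± 0.14). Emcn encodes endomucin, a sialomucin of endothelium, and Calcrl the receptor through which adrenomedullin acts on it. Lyve1 encodes a hyaluronan receptor used as a marker of lymphatic vessels. The largest adjusted p among these 8 genes was 3.99e-07, for Emcn (limma). Toward SVEC4-10 they were Bgn (-7.65 ± 0.16), Upk1b (-7.47 ± 0.21), Dcn (-7.38 ± 0.21), Lox (-7.25 ± 0.21), Scel (-6.87 ± 0.14), Stk26 (-6.77 ± 0.13), Upk3b (-6.74 ± 0.15) and Ptprq (-6.64 ± 0.12). Bgn encodes the proteoglycan biglycan, Lox the enzyme that crosslinks collagen, and Upk1b and Upk3b are uroplakins of the urothelial surface. The largest adjusted p among these was 3.29e-07, for Lox (limma). A dimmer probe set of Bgn gave -3.15. In SVEC4-10, Ms4a6d (2.04), Emcn (3.56) and Chil5 (3.65) lay below the 25th percentile of mouse genes (4.33), as did Dcn, Lox, Scel and Stk26 in mouse LEC, so the size and order of these differences depend on dim values.

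**Figure D1:**
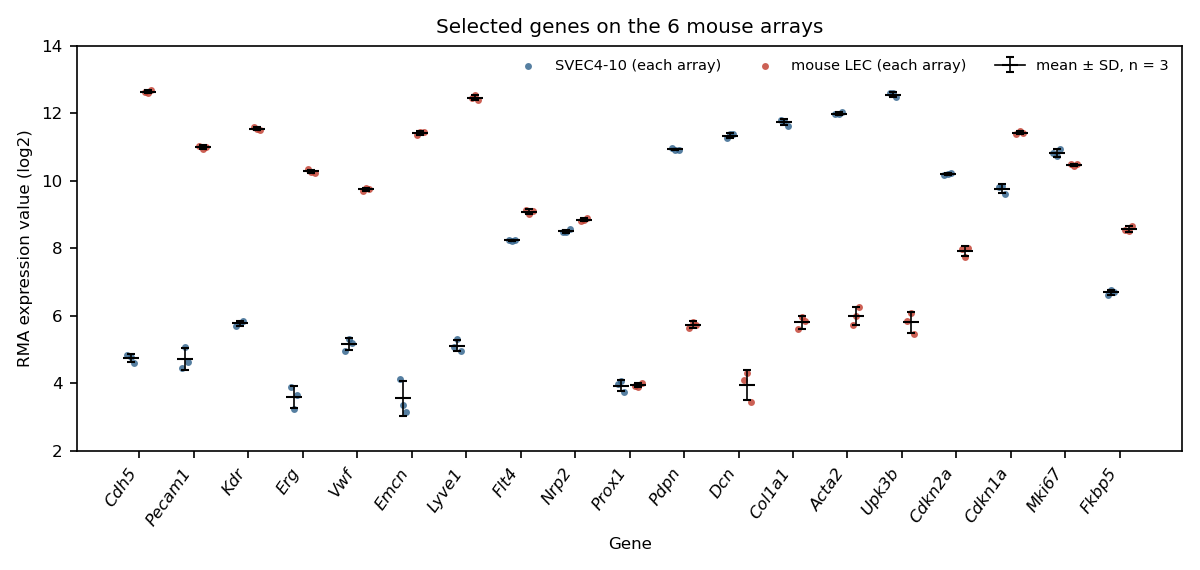
RMA expression values (log2, vertical axis) of 19 genes on each of the 3 SVEC4-10 arrays (blue) and 3 mouse LEC arrays (red), with the mean and SD of each group in black. Cdh5, Pecam1, Kdr, Erg, Vwf, Emcn and Lyve1 lie high in mouse LEC and Pdpn, Dcn, Col1a1, Acta2 and Upk3b high in SVEC4-10, while Prox1 lies near 3.9 in both.

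All 25 measured pan-endothelial genes were higher in mouse LEC, with a median log2 difference of 5.22 (camera adjusted p = 9.36e-24). Erg, an endothelial transcription factor, differed by 6.68 ± 0.16 (SE), Pecam1 (CD31) by 6.26 ± 0.16 and Kdr, the main VEGF receptor, by 5.76 ± 0.08. The smallest difference of the list was 1.28 for Tal1. The median level of these genes was 10.28 in mouse LEC and 5.12 in SVEC4-10, where the median over all genes was 5.65 on the 6 arrays. Of 23 blood vascular endothelial genes, 16 were higher in mouse LEC and 1 in SVEC4-10, with a median of 2.12 (adjusted p = 6.15e-10). Apln, the ligand apelin, differed by 5.93 ± 0.13, Plvap, a protein of endothelial fenestrae, by 5.66 ± 0.14 and Vwf by 4.58 ± 0.10, while Hey2, a Notch target, was higher in SVEC4-10 (-1.91 ± 0.11).

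The lymphatic endothelial genes went both ways. Of 21 measured, 6 were higher in mouse LEC, 4 in SVEC4-10 and 11 were not called, with a median of 0.25 (adjusted p = 0.148). Besides Lyve1, Sox18 (4.90 ± 0.16, SE) and Gata2 (2.80 ± 0.08), both transcription factors of lymphatic development, were higher in mouse LEC. Pdpn, the mucin podoplanin, which fibroblasts and mesothelial cells also carry, was higher in SVEC4-10 (-5.19 ± 0.08), as was Sema3d (-5.83 ± 0.11). Prox1, the transcription factor that specifies lymphatic identity, measured 3.95 ± 0.06 (SD, n = 3) in mouse LEC and 3.93 ± 0.17 in SVEC4-10 (difference 0.014, limma adjusted p = 0.939), below the median gene in both. Flt4, the VEGF-C receptor, differed by 0.85 ± 0.07 (SE) and Nrp2, its co-receptor, by 0.34 ± 0.07, with limma adjusted p of 7.78e-05 and 0.00808, both under 2-fold. Ccl21a was not analysed here, since its probe sets name several genes.

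Markers of other cell types separated the groups unevenly. Of 22 fibroblast genes, 12 were higher in SVEC4-10 and 0 in mouse LEC, with a median of -1.93 (camera adjusted p = 1.86e-07). Besides Dcn these included the collagen genes Col1a1 (-5.93 ± 0.11, SE) and Col5a2 (-5.57 ± 0.09), whereas Lum (0.062), Thy1 (0.027) and Fap (0.10) were not called and lay below the median gene in both groups. Of 16 smooth muscle and pericyte genes, Acta2, encoding smooth muscle actin (-5.99 ± 0.14), and Tagln (-5.16 ± 0.13) were higher in SVEC4-10, Mcam, which endothelium also expresses, was higher in mouse LEC (2.36 ± 0.08), and 13 were not called (median -0.11, adjusted p = 0.147). Of 17 keratinocyte genes only the integrin Itgb4 was called, higher in mouse LEC (2.10 ± 0.14), with a median of 0.033 (adjusted p = 0.622) that was -0.011 without SVEC4-10 replicate 3. Of 20 leukocyte genes, the lysosomal Cd68 was higher in mouse LEC (3.82 ± 0.08) and Cd14 in SVEC4-10 (-1.15 ± 0.07). Their median was -0.028 and their mean 0.10 (adjusted p = 0.969), and Ptprc, the leukocyte antigen CD45, measured 2.91 and 3.13.

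**Figure D2:**
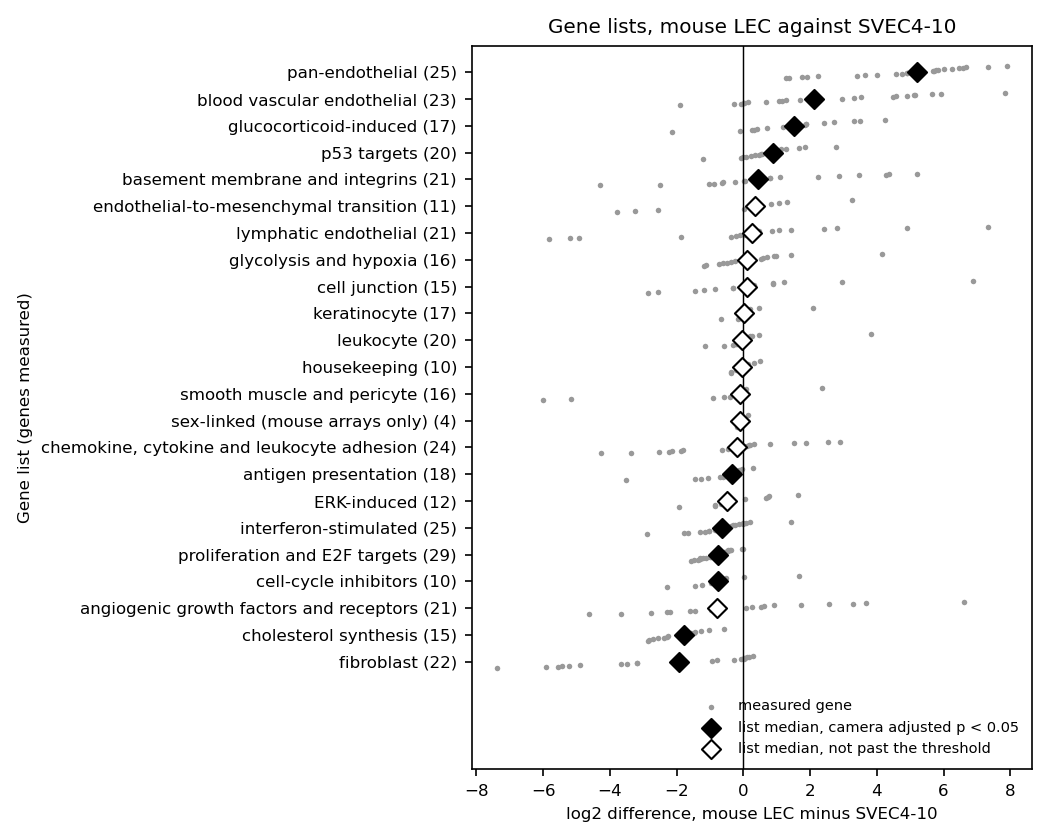
Log2 difference, mouse LEC minus SVEC4-10 (horizontal axis), of each measured gene (grey points) of the 23 gene lists (vertical axis, number of genes in brackets), with list medians as diamonds, filled where the camera adjusted p is under 0.05. The pan-endothelial median lies at 5.22 and the fibroblast median at -1.93.

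Cell division genes as a list were higher in the line. Of 29 proliferation and E2F target genes, 8 were called higher in SVEC4-10 and 0 in mouse LEC, with a median of -0.75 (camera adjusted p = 3.39e-12). The called genes included Cdt1, which licenses replication origins (-1.58 ± 0.07, SE), and the helicase subunits Mcm7 (-1.49 ± 0.07) and Mcm4 (-1.35 ± 0.07), while Mki67 differed by -0.36 ± 0.08 (limma adjusted p = 0.0133). Of 20 p53 targets, 8 were higher in mouse LEC and 1 in SVEC4-10, with a median of 0.89. The list's camera adjusted p was 9.81e-07, and the adjusted p was 0.0514 with an estimated correlation. The receptor Eda2r (2.79 ± 0.11), Zmat3 (1.85 ± 0.10) and Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (1.66 ± 0.09), were higher in mouse LEC, and Sesn1 in SVEC4-10 (-1.20 ± 0.11). Of 10 cell-cycle inhibitor genes, Cdkn2a, encoding p16 and p19ARF (-2.28 ± 0.10), Cdkn2c (-1.43 ± 0.07) and Cdkn1b (-1.23 ± 0.07) were higher in SVEC4-10 and only Cdkn1a in mouse LEC. Their median was -0.77 (camera adjusted p = 0.00113), with adjusted p = 0.140 under an estimated correlation. Trp53 was not analysed here.

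Among immune genes, 7 of 25 interferon-stimulated genes were higher in SVEC4-10 and 1 in mouse LEC, with a median of -0.64 (camera adjusted p = 2.30e-06). The nucleic acid sensor Zbp1 (-2.88 ± 0.09, SE), the antiviral Mx1 (-1.78 ± 0.14) and Isg15 (-1.66 ± 0.07) were higher in SVEC4-10 and Oas3 in mouse LEC (1.44 ± 0.07). Of 18 antigen presentation genes, 4 were higher in SVEC4-10 and 0 in mouse LEC. They were the class I gene H2-K1 (-3.51 ± 0.08), Tapbp (-1.44 ± 0.07), Nlrc5 (-1.28 ± 0.17) and Tap1 (-1.05 ± 0.07). The list's median was -0.34 (camera adjusted p = 0.000903), with adjusted p = 0.0514 under an estimated correlation. H2-K1 sequences differ between mouse strains, and a dimmer probe set of Tapbp gave -0.51. Of 24 chemokine, cytokine and leukocyte adhesion genes, 7 were higher in SVEC4-10 and 4 in mouse LEC (median -0.20, adjusted p = 0.208). The chemokines Cxcl10 (-4.25 ± 0.08), Ccl5 (-3.35 ± 0.12) and Ccl7 (-2.51 ± 0.17) stood on the SVEC4-10 side, and the scavenger receptor Ackr3 (2.90 ± 0.10) and Il6 (2.53 ± 0.22) on the mouse LEC side.

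Growth factor, junction and matrix genes moved in both directions. Of 21 angiogenic growth factor and receptor genes, 5 were higher in mouse LEC, led by placental growth factor Pgf (6.62 ± 0.10, SE) and adrenomedullin Adm (3.68 ± 0.18). A further 7 were higher in SVEC4-10, led by the receptors Egfr (-4.61 ± 0.09) and Igf1r (-3.66 ± 0.14) and by Bmp4 (-2.76 ± 0.08), and the median was -0.80 (camera adjusted p = 0.436). Of 15 cell junction genes, Jam2 (6.88 ± 0.07), occludin Ocln (2.97 ± 0.13) and Tjp1 (1.23 ± 0.08) were higher in mouse LEC and 4 in SVEC4-10, including connexin 43, encoded by Gja1 (-2.87 ± 0.07), and N-cadherin, encoded by Cdh2 (-2.54 ± 0.09). Their median was 0.11 (adjusted p = 0.969). Of 21 basement membrane and integrin genes, 7 were higher in mouse LEC, led by the laminin chain Lama4 (5.20 ± 0.13) and the integrins Itgb3 (4.37 ± 0.07) and Itga2 (4.28 ± 0.23). Nid2 (-4.29 ± 0.08), fibronectin Fn1 (-2.49 ± 0.07) and Itgav (-1.03 ± 0.09) were higher in SVEC4-10. The list's median was 0.44 (camera adjusted p = 0.0476, and adjusted p = 0.140 with an estimated correlation). Its adjusted p was 0.0539 without mouse LEC replicate 1, 0.0585 without mouse LEC replicate 3 and 0.0587 without SVEC4-10 replicate 2.

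Of 11 measured genes listed for endothelial-to-mesenchymal transition, 3 were called in each direction. Tgfbi (3.25 ± 0.16, SE), Tgfb1 (1.32 ± 0.08) and Zeb1 (1.06 ± 0.10) were higher in mouse LEC, and Tgfb2 (-3.77 ± 0.10), Inhba (-3.26 ± 0.34) and S100a4 (-2.55 ± 0.13) in SVEC4-10. Their median was 0.36 and their mean -0.18 (camera adjusted p = 0.217), and Zeb1 differed by 0.97, under 2-fold, without SVEC4-10 replicate 2.

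Nearly all cholesterol synthesis genes were higher in SVEC4-10. Of 15 measured cholesterol synthesis genes, 14 were higher in SVEC4-10 and 0 in mouse LEC, with a median of -1.79 (camera adjusted p = 3.39e-12). The sterol pathway enzymes Lss (-2.85 ± 0.07, SE), Cyp51 (-2.83 ± 0.11) and Fdps (-2.69 ± 0.10) differed most, and Mvk differed by -0.58. Of 16 glycolysis and hypoxia genes, the oxygen sensor Egln3 (4.15 ± 0.09) and the glucose transporter Slc2a1 (1.44 ± 0.07) were higher in mouse LEC, and P4ha1 (-1.18 ± 0.07) and the lactate transporter Slc16a3 (-1.13 ± 0.17) in SVEC4-10, with a median of 0.11 (adjusted p = 0.490). Slc16a3 differed by -0.94 without SVEC4-10 replicate 2, and a dimmer probe set of Slc2a1 gave 0.52.

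Glucocorticoid-induced genes were higher in the cells grown with hydrocortisone. Of 17, 11 were higher in mouse LEC and 1 in SVEC4-10, with a median of 1.51 (camera adjusted p = 3.49e-08). Lcn2 (4.26 ± 0.10, SE), Ddit4 (3.49 ± 0.07), Rasd1 (3.31 ± 0.10) and Fkbp5, a chaperone of the glucocorticoid receptor (1.88 ± 0.08), were higher in mouse LEC, and the metallothionein Mt2 in SVEC4-10 (-2.14 ± 0.08). Of 12 ERK-induced genes, Spry4 was higher in mouse LEC (1.65 ± 0.08) and Phlda1 in SVEC4-10 (-1.93 ± 0.10), with a median of -0.50 (adjusted p = 0.561). None of 10 housekeeping genes was called by limma at 2-fold, although 3 had an adjusted p under 0.05 (median -0.047, camera adjusted p = 0.969). None of the 4 measured sex-linked mouse genes was called, and 0 had an adjusted p under 0.05 (median -0.11, camera adjusted p = 0.969). Xist measured 3.40 ± 0.39 (SD, n = 3) in mouse LEC and 3.58 ± 0.21 in SVEC4-10. The Y-linked Eif2s3y measured 8.30 ± 0.05 and 8.15 ± 0.07, Kdm5d 6.84 ± 0.09 and 6.90 ± 0.20, and Uty 7.39 ± 0.06 and 7.56 ± 0.23, in the same order.

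Over the 23 lists, camera with its preset correlation of 0.01 called 5 higher in mouse LEC and 6 higher in SVEC4-10. With an estimated correlation the calls of the pan-endothelial, blood vascular endothelial, glucocorticoid-induced, fibroblast, proliferation, interferon-stimulated and cholesterol lists held. For each of the 23 lists, the counts of called genes in each direction adjusted over the list alone equalled those over all genes tested.

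Human values are given gene by gene, and since brightness depends on the probes they do not rank genes by abundance. LYVE1 measured 11.76 and NRP2 8.65, each identical on all 3 arrays. KDR measured 11.04 ± 0.02 (SD, n = 3), VWF 10.10 ± 0.07 and PECAM1 10.27, identical on all 3. PROX1 measured 4.60 ± 0.06, FLT4 5.76 ± 0.26, and PDPN 4.06 and CCL21 4.26, each identical on all 3 arrays. A brighter probe set of such a gene may be among the 37519 human probe sets without a listed gene, so a dim value does not show low expression. Of the genes that led the mouse comparison, CALCRL measured 9.53, EMCN 8.89 and CEACAM1 5.08 ± 0.12 in human LEC. On the SVEC4-10 side, BGN measured 10.15 ± 0.03, LOX 10.54 ± 0.03, STK26 6.01 ± 0.13, UPK3B 4.03, UPK1B 3.24, DCN 1.90 and SCEL 1.32. Gene values given without an SD were identical on all 3 arrays. Human counterparts of Cdh5, Ms4a6d, Chil5, Tc2n and Ptprq were not analysed here.

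All 21 measured human pan-endothelial genes lay above the human gene median of 4.65, with a list median of 8.17. The blood vascular list had a median of 6.26 (16 of 18 genes above the gene median), the lymphatic list 5.38 (10 of 17) and the fibroblast list 4.23 (4 of 9). Medians were 6.78 for smooth muscle and pericyte genes, 3.56 for keratinocyte genes and 3.51 for leukocyte genes. Human levels were not tested against mouse levels, since the designs differ in their probes. The housekeeping gene GAPDH measured 5.53 ± 0.02 (SD, n = 3) on the human arrays, and the 5 measured human housekeeping genes had a median of 6.41.

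The comparison across species asks which mouse cells had the profile closer to human LEC. Over 10085 genes matched by symbol, the correlation with the mean of the human arrays was 0.722 ± 0.002 (SD, n = 3) for mouse LEC and 0.712 ± 0.001 for SVEC4-10. All 3 mouse LEC arrays lay above all 3 SVEC4-10 arrays, by 0.00997 on average. In an exact permutation test, two-sided over 20 splits, p = 0.10, the smallest value that 3 arrays against 3 can give. Genes are not independent replicates, and these correlations are across genes. Over the 1503 matched genes called in the mouse comparison, the correlations were 0.436 for mouse LEC and 0.328 for SVEC4-10, a difference of 0.108 (exact permutation p = 0.10). These genes were chosen for differing between the mouse groups, which by itself favours a wider gap. Both primary cultures received medium additives that SVEC4-10 did not, so closeness by medium and by cell type cannot be told apart. Over genes above the median mouse level the correlations were 0.530 and 0.499, a difference of 0.0310, and over the alternatives the difference ranged from 0.00688 to 0.108.

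The human level of the genes that separated the mouse groups was compared with that of random lists. The 684 matched genes called higher in mouse LEC had a median human value of 5.85, at percentile 17.2 of 10000 random lists matched on mouse level (random median 5.90, central 95% from 5.78 to 6.04). The 819 called higher in SVEC4-10 had a median of 5.62, at percentile 8.15 (random median 5.71, central 95% from 5.58 to 5.84). The percentiles were not stable and are not interpreted. Without mouse LEC replicate 1, 2 or 3 they were 96.86, 99.03 and 99.04 for the genes higher in mouse LEC, and 0, 0 and 0.03 for those higher in SVEC4-10. Without SVEC4-10 replicate 1, 2 or 3 they were 0.04, 0 and 0.27, and 94.00, 97.52 and 95.64. The level used for matching is the mean over the mouse arrays, so leaving out 1 array gives the other group more weight in it. Without matching both percentiles were 100, and over all alternatives they ranged from 0 to 100.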

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

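The counts of this part were made after the main comparison had been seen, and no explanation was tested for them. Probe sets outside the gene comparison also differed between the mouse groups (limma, adjusted over every probe set). Of 16010 mouse probe sets with no gene listed, 465 were at least 2-fold higher in mouse LEC and 274 in SVEC4-10, 4.62% of them. Of 1814 probe sets that name several genes, 70 were higher in mouse LEC and 111 in SVEC4-10, 9.98% of them. No biological explanation was tested.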

How the results depend on the processing

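All alternatives of this part were planned. With other scalings, dim-gene filters, probe set means, variance models or array weights, counts of called genes stayed within 1.5 times the reported 1180 and 1368. Without a fold minimum they were 3762 and 4259, at 4-fold 480 and 461, with limma's treat test 780 and 789, and over every probe set 1812 and 1795. Most of these settings change the threshold or the features by construction. Lists called higher in mouse LEC and in SVEC4-10 numbered 3 and 4 with an estimated correlation and 10 and 9 with fry, which tests another question, against 5 and 6. Samples with the same number did not deviate together (correlations 0.041, 0.069 and -0.015), and the replicate block gave 1180 and 1367 genes and 4 and 6 lists, changing among lists only the call of basement membrane and integrins (adjusted p = 0.0611). That list also lost its call with 3 scalings and both dim-gene filters (0.0536 to 0.122). Medians of uncalled lists changed sign for cell junction (-0.10 with either dim-gene filter), leukocyte (1.33 among genes above the median), glycolysis (-0.0080 with probe set means) and keratinocyte (-0.011 without SVEC4-10 replicate 3). Fewer members remained under the filters; otherwise the cause was not tested. The median human level of genes higher in mouse LEC was 5.88 with median centring, 5.87 and 5.97 with the dim-gene filters, and 5.77 with probe set means and at 4-fold. That of genes higher in SVEC4-10 was 5.81 with the stricter filter, 5.52 with probe set means and 5.26 at 4-fold, and the cause was not tested. Similarity differences were 0.0143 and 0.0310 with the dim-gene filters, against 0.00997. Leaving out each array in turn gave 1158 to 1205 and 1342 to 1398 genes, 4 to 5 lists and 6 lists, human medians of 5.83 to 5.92 and 5.61 to 5.68 (at percentiles from 0 to 99.04 and 0 to 97.52, against 17.2 and 8.15), similarity differences of 0.00917 to 0.0107 and a keratinocyte median of -0.011 to 0.090. Of 99 named genes, 72 stayed on their side of the threshold in every alternative that tests them. The other splits of the 6 mouse arrays are too few for a share under 0.05. The real split called 2548 genes and 1 of 10 splits reached that, with 0 genes at most in any other split. Each other split mixes arrays of both groups, so the large differences between the groups enter its residual spread. Few calls were possible there, and the 0 decides nothing. Signal over background limits dim genes such as Prox1, whose change cannot be read from these values.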

Other observations

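The tests of this part that were chosen only after their result was seen are those of exchanged labels by gene lists, of scaling, of the Prox1 level and of the identical human values. The tests of mesothelial markers and of strain-dependent genes were written before their values were seen. Since Upk3b and Upk1b, which mesothelial cells also express, led the comparison, 15 mesothelial markers were listed, of which 5 had been seen among the leading genes and 0 belong to a fixed list. Of the 10 not seen before, 6 were called higher in SVEC4-10 and 0 in mouse LEC. Msln, encoding mesothelin, measured 5.50 ± 0.16 (SD, n = 3) in mouse LEC and 10.33 ± 0.02 in SVEC4-10, and the transcription factor gene Wt1 5.28 ± 0.21 and 9.76 ± 0.16. Rspo1 (-3.38), Lrrn4 (-2.07), Muc16 (-1.55) and Nkain4 (-1.49) were also higher in SVEC4-10. The keratins Krt19 (-0.031), Krt8 (-0.14) and Krt18 (-0.21), and Aldh1a2 (-0.064), were not called, and in SVEC4-10 they measured 4.89, 5.91, 5.03 and 4.53, dim or near the gene median of 5.65. In SVEC4-10, Upk3b measured 12.55 and Upk1b 12.29.

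The pan-endothelial genes that were far lower on the arrays labelled SVEC4-10 raise the question of what those arrays measured. Of the 25 measured, 21 differed at least 4-fold, and the median level of the list in SVEC4-10 was 5.12. Not all were dim there: Fli1 (8.31 to 8.46) and Ets1 (7.52 to 7.71) lay well above the gene median of 5.65 on the SVEC4-10 arrays. An exchange of the labels of both mouse groups was argued against by the medians of the glucocorticoid-induced (1.51), p53 target (0.89) and proliferation (-0.75) lists, which lay on the sides that a hydrocortisone medium and SV40 transformation predict, though the p53 list had adjusted p = 0.0514 with an estimated correlation. Nnt (-1.20) and Glo1 (-0.45, under 2-fold) carry a deletion in some C57BL/6 mice and a duplication in some other strains. Both lay on the side predicted for labels as given. They cannot decide on an exchange, since the labels give no strain for the line. Moreover, 4259 of 22180 genes were higher in SVEC4-10 at a limma adjusted p under 0.05. The housekeeping median was -0.047 in the normalized values. It cannot decide on scaling before normalization, since RMA had made the distributions of the arrays equal. Cells with mesothelial-like expression on the SVEC4-10 arrays stay a candidate source. The median of the 10 markers not seen before was -1.52, below all 10000 random lists matched on level. Those lists draw genes independently and make no allowance for markers that vary together, so their range is too narrow for a test. The uncalled keratins, which mesothelial cells carry, go against a full mesothelial profile unless their probe sets do not respond. Whether the line lost its endothelial genes in culture, whether the stock held another cell, or whether medium and cell type account for the difference stays open and was not tested.

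Prox1 and Reln, both lymphatic markers, were dim on all 6 mouse arrays. Of the same list 6 genes were called higher in mouse LEC, among them Lyve1 (12.46 there), Sox18 (10.01), Gata2 (9.70) and Itga9 (7.92). Flt4 measured 9.08 in mouse LEC and 8.23 in SVEC4-10, under 2-fold apart, so its level does not set the groups apart. The 4 list genes called higher in SVEC4-10 measured low in mouse LEC: Pdpn 5.74, Maf 4.67, Mmrn1 4.60 and Sema3d 3.76. In SVEC4-10 Pdpn measured 10.92, Maf 9.59 and Sema3d 9.59, so unresponsive probe sets do not account for their low values. A culture in which lymphatic cells are a minority beside blood vascular endothelial cells might give the dim genes. The median level in mouse LEC was 8.88 for the blood vascular list and 6.14 for the lymphatic list. Neither these levels nor single list members decide on such a culture, since the brightness of a probe set gives no share of cells. The median log2 difference between the mouse groups was larger by 1.87 for the blood vascular list than for the lymphatic one. This decides nothing, since lymphatic list genes high in SVEC4-10 such as Pdpn and Sema3d enter it. Probe sets that do not respond might give dim Prox1 and Reln values too, since Prox1 reached at most 4.09 on any mouse array against a gene median of 5.65. These cannot be told apart, because no array here holds RNA known to contain mouse Prox1.

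More than 1 in 2 human probe sets (54.2%) held identical values on all 3 human arrays, against 0 of the mouse probe sets on 6 arrays, and 38.4% of the 151 named human probe sets above 10 did so. Deposition of 1 hybridisation 3 times was argued against, since 45.8% of probe sets differed between arrays. Median polish of arrays with independent noise might give such ties. In simulation over 3 arrays it tied 0% of probe sets of 4 probes, 7.5% of 8, 23.2% of 12, 54.1% of 20 and 88.5% of 40. Over 6 arrays it tied 0. The simulated arrays shared 1 true level per probe set and differed by noise alone. Real differences between separate cultures were therefore not covered. Whether median polish accounts for the share cannot be told apart from other causes here. The simulated share at 12 probes was under the bound of 25% set for it. Different probe sets also shared values within 1 array: human array 1 held 18269 distinct values over 53617 probe sets, mouse array 1 38238 over 41345. The simulation did not cover such ties between probe sets, and their cause was not tested. Hybridisation of 1 RNA 3 times also stays open, as the ties hide small differences and the 95th percentile of the SD over genes was 0.201; no biological explanation was tested.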
